A study of Mus musculus with 10 samples.

How the data were processed

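Total RNA from cardiac tissue in 10 samples from male mice was profiled, 5 samples labelled HIPK2 knockout and 5 labelled wild type, each hybridised alone to a 1-colour Agilent array. Per the labels' protocols, tissue was snap-frozen, RNA was isolated with a mirVana kit, and cyanine-3 labelled cRNA was made by linear amplification. Groups and replicate numbers were taken from the sample titles. The labels number the replicates within each genotype and do not say outright that each came from a separate mouse, so the p-values measure the spread between these samples.

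The deposited array files hold spot intensity on a linear scale, written by Agilent Feature Extraction 10.7.1.1, a version credited to the submitters' processing notes. Per the file headers, the processed intensity was background-subtracted and detrended within each array by that software, with no scaling between arrays, and spot mean intensity and local background medians were given beside it. The authors also deposited a value table of the same arrays on a log2 scale. Set against the scanner values, its columns correlated with their own arrays at r of 0.704 to 0.983 across probes, after removal of each probe's mean, against at most 0.241 for any other array. All 10 of its columns share a median of 4.74 and a maximum of 18.6, as quantile normalization gives. Its filtering and background treatment were not given in the sources used here, and it served only as an alternative.

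For the main values, log2 of the processed signal was taken and the log2 of each array's 75th percentile, over the 59305 spots that are not controls, was subtracted. Control spots and spots marked as outliers by the software were left out, and spots of one probe were averaged, giving 56605 probes. A probe was kept if it was well above background on at least 4 of the 5 arrays of at least 1 genotype, which left 30693 probes. Gene names were taken by matching the array's accession to a RefSeq gene table, which named 32994 probes; the other 23611 kept the name in the array file. A gene was represented by its kept probe with the highest mean signal, which left 20607 genes, of which 6847 had several kept probes. Probe positions are those of the array files, on mouse build mm9; exon and intron annotation of that build was not used here.

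Knockout and wild type were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, without covariates, and p-values were adjusted over genes by the method of Benjamini and Hochberg, with a threshold of 0.05. Fold changes are on the log2 scale, knockout minus wild type, with the standard error (SE) of the fit. For named genes whose probe was well above background on at most 3 arrays of the dimmer genotype, the fold is a lower bound. Per array of the dimmer genotype, the higher of the probe's own signal and the lowest signal among probes well above background was taken. The mean of the brighter genotype was set against the mean of these values. The bound holds for the software's background subtraction only, and another background correction can give a smaller fold. Tested on simulated data for the 20607 genes of this comparison, with 200 genes changed, the fit recovered 21.5% of genes changed by 0.5 on the log2 scale, 70.5% of those changed by 1 and 97.5% of those changed by 2. Of the calls, 0%, 4.08% and 7.58% were false in these 3 runs, the last above the 5% aimed at. The simulated noise was independent between genes and held no tissue differences, so these rates need not hold for the real arrays.

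The 30 gene lists, covering pathways, cell type markers of heart and neighbouring tissue, the genes flanking Hipk2 and its family and partners, were fixed before the data were examined. So were the test, the filter, the alternatives and the rule for named genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, served as alternatives. The 10 genes with a missing value on some array were left out of the list tests. The named genes are Hipk2 with every probe, and the 12 largest rises and 12 largest falls among genes past the threshold whose knockout values all lay on one side of the wild-type values, leaving out clone, predicted-gene and accession names. From each list they include up to 4 members past the threshold by smallest adjusted p, or up to 2 that pass when adjusted over the list alone, or else up to 2 with the smallest p given as values. Other genes named were chosen after their values were seen and are marked where they appear.

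Single values per array were compared by two-sided exact permutation over the 252 arrangements of 10 arrays, for which 0.00794 is the smallest p. Per the file headers the arrays lay on 2 slides, and each slide had its own scan. Alternatives were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, a filter asking for signal on all 10 arrays, the mean over a gene's probes, an intensity trend, array weights, replicate number or slide as a block, the authors' value table, and each array left out in turn. Fits within slide 2, with slide and row, with tissue scores as covariates, and the exact permutation of list means, also with each member left out, were chosen after seeing the data. The number of arrays limits the precision of every value. No sample was left out of the main comparison.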

Results

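Cardiac gene expression was compared between male mice labelled HIPK2 knockout and wild type, with 5 samples per genotype. HIPK2, homeodomain interacting protein kinase 2, is a nuclear kinase that phosphorylates transcriptional regulators, among them p53. Per the series description, the knockout was made on the C57BL/6 background by CRISPR, which removed 56 bases in the second exon of the gene and shifted its reading frame. The comparison asks which transcripts differ in the heart when the kinase is missing. The 75th percentile of spot signal was 378 ± 75.3 on knockout arrays and 499.5 ± 31.9 on wild-type arrays (SD, n = 5 each), and every knockout array lay below every wild-type array (two-sided exact permutation p = 0.00794, the smallest that 5 against 5 can give). The share of spots well above background was 51.9% ± 5.36 in knockout and 58.6% ± 1.8 in wild type (exact permutation p = 0.0397). Signal of the E1A control spots, RNA added in fixed amount, was 10.72 in knockout and 10.80 in wild type on the log2 scale (exact permutation p = 0.151). No spot was saturated on any array. Slide 1 carried only wild-type replicates 1 and 2, and slide 2 carried the other 8 arrays.

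Markers of atrium, fat and macrophages varied among the samples, whose labels give cardiac tissue without naming the part of the heart. The atrial score, the mean log2 signal of Myl7, Myl4 and Sln relative to the array's 75th percentile, was -0.45 ± 1.74 in knockout and 2.25 ± 3.12 in wild type (SD, n = 5; exact permutation p = 0.127). Wild-type replicate 1 had the lowest atrial score of the 10 arrays, -3.02, and wild-type replicate 2 the highest, 4.81. The fat score over Cfd, Car3, Cidec and Retn was -4.24 ± 0.81 in knockout and -2.34 ± 1.67 in wild type (exact permutation p = 0.0397). The macrophage score over 9 core markers, Cd68, Csf1r, Adgre1, C1qa, C1qb, C1qc, Mrc1, Lyz2 and Laptm5, was 1.69 ± 0.25 in knockout and 2.04 ± 0.105 in wild type (exact permutation p = 0.0159). After Benjamini-Hochberg adjustment over the 6 array measures compared, the p-values were 0.0476 for signal, 0.0596 for spots above background, 0.151 for the atrial score, 0.0596 for the fat score, 0.0477 for the macrophage score and 0.151 for E1A.

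**Figure D1:**
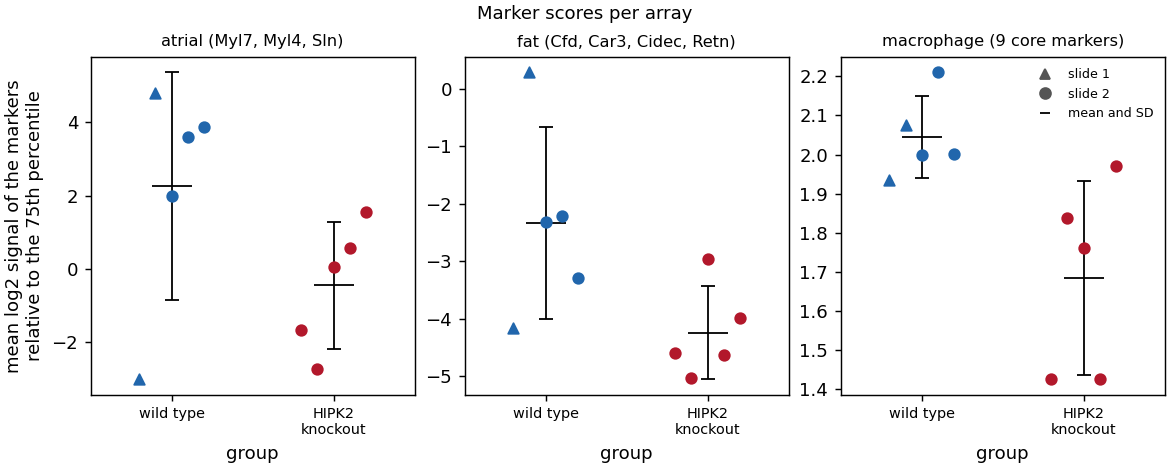
Atrial, fat and macrophage marker scores of each array, as mean log2 signal relative to the array's 75th percentile, for wild-type and HIPK2 knockout samples; triangles are arrays on slide 1, circles arrays on slide 2, and bars the mean with SD. The fat score was -4.24 in knockout and -2.34 in wild type, and 1 wild-type array had an atrial score of -3.02.

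Hipk2 transcript signal did not separate the genotypes. The array holds 3 Hipk2 probes, all on chromosome 6 of mm9 and all well above background on all 10 arrays. The brightest, at 38648097 to 38648156, had a knockout mean of 1.58 ± 0.25 and a wild-type mean of 1.54 ± 0.31 (SD, n = 5), a difference of 0.04 ± 0.17 (SE) with a 95% interval of -0.33 to 0.40 (limma adjusted p = 0.902). The probe at 38768232 to 38768291 differed by 0.11 ± 0.10 (interval -0.10 to 0.32, adjusted p = 0.473). The probe at 38693102 to 38693161 differed by -0.01 ± 0.09 (interval -0.21 to 0.19, adjusted p = 0.96). None of the 3 probes shares 15 bases in a row with the deleted sequence, and shorter overlaps were not tested. The probes showed no loss of Hipk2 transcript, so the knockout here rests on the labels and the series description.

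**Figure D2:**
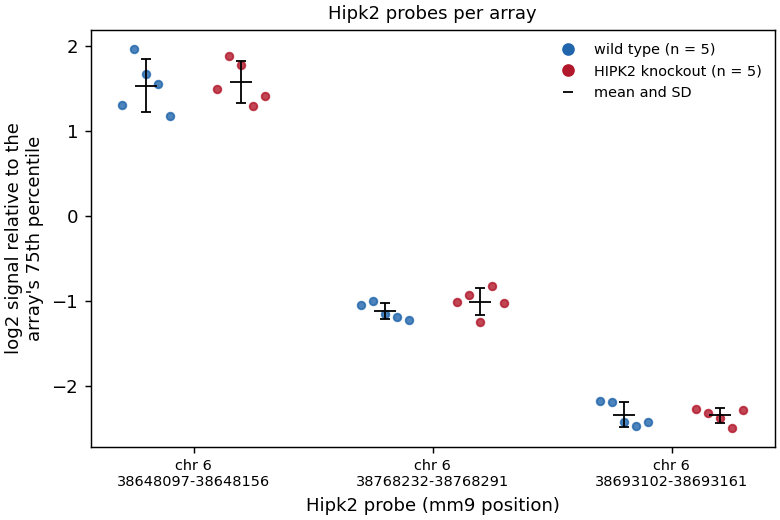
Log2 signal of the 3 Hipk2 probes relative to the array's 75th percentile, for each wild-type and HIPK2 knockout array, with the mean and SD; the horizontal axis gives each probe's mm9 position. The values of both genotypes overlap at every probe, with adjusted p of 0.902, 0.473 and 0.96.

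Of 20607 genes tested, 405 rose and 612 fell in knockout hearts (limma adjusted p under 0.05), 4.94% of all genes. Among them 145 changed at least 2-fold by the fitted value, 29 upward and 116 downward. For 892 of these 1017 genes, and for 1850 genes or 8.98% of all, the 5 knockout values did not overlap the 5 wild-type values, where chance alone gives 0.794%. At an unadjusted p under 0.05 there were 5602 genes, and the median log2 fold change of all genes was 0.03. Rises made up 39.8% of the calls, against 71.8% (2233 up, 878 down) with normexp background correction. Within slide 2 there were 458 calls (140 up, 318 down), 338 of them among the 1017. With slide as a block there were 774 (246 up, 528 down), 515 of them among the 1017. As slide 1 held no knockout array, both fits give the same fold changes and differ only in the spread used. The number of calls was 434 without knockout replicate 1, 368 without knockout replicate 2, 469 without knockout replicate 4, 381 without wild-type replicate 2, 304 without wild-type replicate 4 and 282 without wild-type replicate 5. With the atrial score as a covariate 57 genes were called, with atrial and fat scores 8, and with slide and row of the array none (2788 at an unadjusted p under 0.05). In these 3 fits all 1017 genes kept their direction, with median sizes of 0.595, 0.599 and 0.607 against 0.615 without covariates. The median SE rose from 0.127 to 0.15, 0.167 and 0.213. The 1017 genes were chosen for passing without covariates on the same arrays, which favours a kept direction and size. Of the 71 genes past the threshold that are named by the rule, 17 kept their call with the atrial score: Cyp2b9, Cyp2b10, Slc9a3, Lgi1, Adcy1, Klhl32, Arrdc2, Cdsn, Fam205a2, Egr3, Slc6a12, Ccl7, Ccl2, Ccl9, Ccl6, Col4a1 and Arntl.

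**Figure D3:**
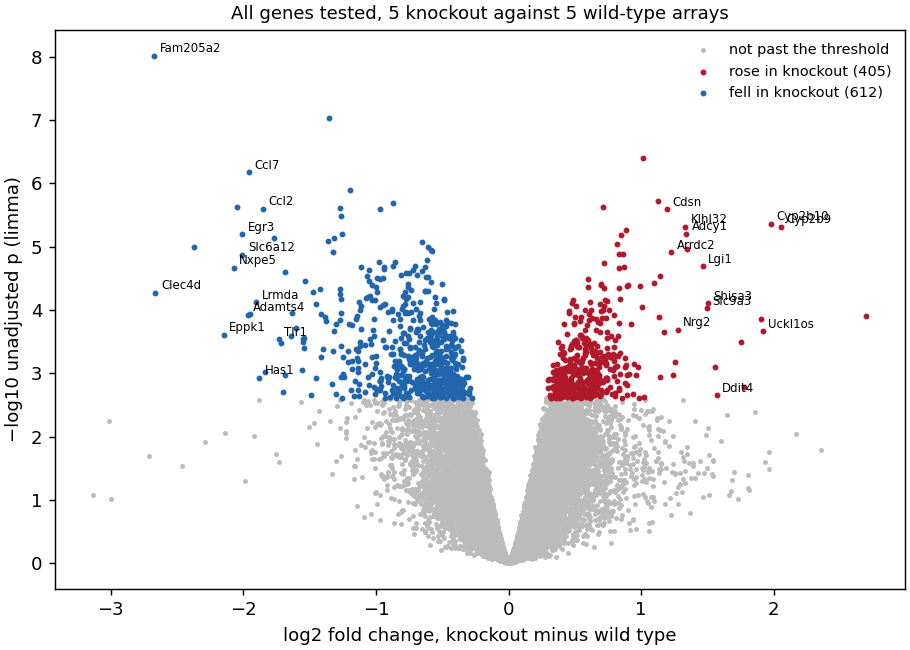
Each point is a gene, with the log2 fold change of knockout minus wild type on the horizontal axis and -log10 of limma's unadjusted p on the vertical axis; coloured genes passed an adjusted p of 0.05 and named genes are the largest rises and falls of the naming rule. There were 405 rises and 612 falls, and Fam205a2 had the lowest p.

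The largest rises were those of Cyp2b9 and Cyp2b10, cytochrome P450 enzymes of foreign compound metabolism on chromosome 7. Cyp2b9 rose 4.16-fold (log2 2.06 ± 0.25, adjusted p = 0.00587) and Cyp2b10 rose 3.95-fold (1.98 ± 0.23, adjusted p = 0.00587). Each was higher in 5 of 5 knockout samples than in any wild-type sample, which the naming rule asks for. Uckl1os, a non-coding transcript opposite Uckl1, rose 3.78-fold (1.92 ± 0.35, adjusted p = 0.0195), and its second probe by 0.95 ± 0.22. Ddit4, an inhibitor of mTORC1, rose 2.97-fold (1.57 ± 0.39, adjusted p = 0.048). Shisa3, which restrains Wnt and FGF signalling, rose 2.84-fold (SE 0.24 on the log2 scale), the sodium-proton exchanger Slc9a3 by log2 1.49 ± 0.25 and the secreted protein Lgi1 by 1.46 ± 0.20. Adcy1, an adenylyl cyclase, rose by 1.34 ± 0.16, Klhl32 by 1.33 ± 0.16, the neuregulin Nrg2 by 1.27 ± 0.23, Arrdc2 by 1.23 ± 0.16 and corneodesmosin, Cdsn, by 1.20 ± 0.13. Adjusted p for these 8 lay between 0.00409 for Cdsn and 0.019 for Nrg2. The Nrg2 probe was dim, well above background on 3 of 5 knockout arrays and 4 of 5 wild-type arrays. With normexp correction all 12 rises kept their call but were smaller, with log2 1.08 for Cyp2b9, 1.41 for Cyp2b10, 1.14 for Uckl1os, 0.95 for Shisa3, 0.78 for Slc9a3, 0.78 for Lgi1, 0.985 for Adcy1, 0.70 for Nrg2 and 0.63 for Cdsn. Ddit4, at 1.48, was then the largest of the 12, with 1.17 for Klhl32 and 1.14 for Arrdc2. The Ddit4 call held in 1 of the 10 fits that leave out an array (adjusted p up to 0.103, without wild-type replicate 2) and gave adjusted p = 0.104 within slide 2. Among those 10 fits, Uckl1os and Nrg2 were each lost in 1, without wild-type replicate 5 (adjusted p = 0.0503 for both). Nrg2 was also lost within slide 2 (adjusted p = 0.0644), and 4 of the 12 rises were lost with the atrial score as a covariate: Uckl1os (adjusted p = 0.0976), Nrg2 (0.0569), Shisa3 (0.0728) and Ddit4 (0.163). Ddit4 also missed the threshold with quantile normalization (adjusted p = 0.0535).

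Among the falls, Clec4d, a C-type lectin of myeloid cells, was 6.33-fold lower in knockout (log2 -2.66 ± 0.42, adjusted p = 0.0119). Adamts4, a protease of cartilage-type proteoglycans, was 3.91-fold lower (-1.97 ± 0.34, adjusted p = 0.0153), Ccl7 was 3.88-fold lower (-1.95 ± 0.19, adjusted p = 0.00345), Lrmda 3.74-fold lower (-1.90 ± 0.31, adjusted p = 0.0135) and Ccl2 3.61-fold lower (-1.85 ± 0.21, adjusted p = 0.00409). Epiplakin, Eppk1, was at least 1.73-fold lower (adjusted p = 0.0206) and not well above background on 3 of 5 knockout arrays. Another 6 genes were not well above background on any knockout array. Fam205a2, at 41841838 to 41841897 on chromosome 4, was at least 1.79-fold lower (adjusted p = 0.000199), the Toll-like receptor Tlr1 at least 1.71-fold (adjusted p = 0.0216) and Nxpe5 at least 1.5-fold (adjusted p = 0.0089). The betaine transporter Slc6a12 was at least 1.35-fold lower (adjusted p = 0.00754), the hyaluronan synthase Has1 at least 1.16-fold (adjusted p = 0.0377) and the transcription factor Egr3 at least 1.15-fold (adjusted p = 0.00625). With normexp correction Nxpe5, Egr3, Slc6a12, Has1 and Tlr1 lost their calls (adjusted p = 0.0904, 0.365, 0.123, 0.429 and 0.355), and the falls were smaller for Fam205a2 (-0.49), Eppk1 (-0.42), Clec4d (-1.40), Adamts4 (-1.05), Ccl7 (-1.38) and Lrmda (-1.15). The folds with normexp were 1.41 for Fam205a2, 1.34 for Eppk1, 1.21 for Nxpe5, 1.19 for Slc6a12 and 1.18 for Tlr1. They were 1.14 for Has1 and 1.13 for Egr3, and each of these lay below its bound above. Has1 lost its call in 7 of 10 fits with an array left out (adjusted p up to 0.0825, without wild-type replicate 4). Eppk1 and Tlr1 each lost it in 2 of 10. Adjusted p reached 0.0528 for Eppk1 without wild-type replicate 5 and 0.0507 for Tlr1 without knockout replicate 2. Eppk1 also lost it within slide 2 (adjusted p = 0.0734). With the atrial score as a covariate, calls were lost for Clec4d (limma adjusted p = 0.0569), Adamts4 (0.0794), Lrmda (0.0622) and Has1 (0.1365). Lost too were Eppk1 (0.0976), Nxpe5 (0.0551) and Tlr1 (0.0992), while Fam205a2, Egr3, Slc6a12, Ccl7 and Ccl2 kept theirs. The Clec4d and Lrmda probes were well above background on 4 of 5 knockout arrays.

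**Figure D4:**
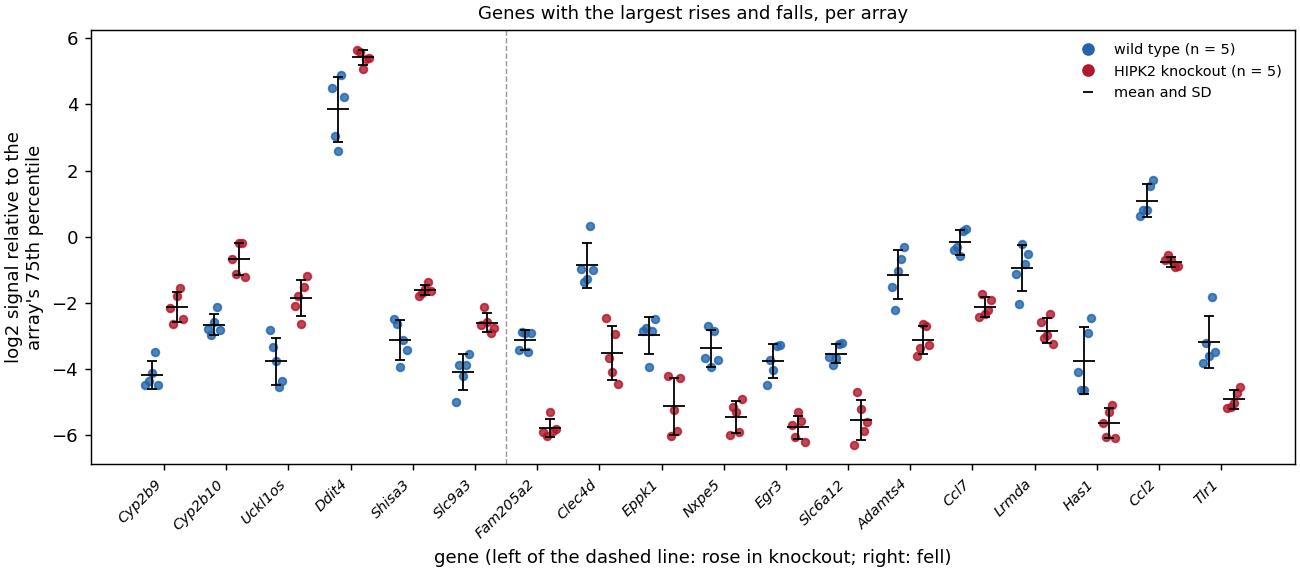
Log2 signal relative to the array's 75th percentile of the 6 largest rises and 12 largest falls, for each wild-type and HIPK2 knockout array, with the mean and SD. The naming rule takes only genes whose knockout and wild-type values do not overlap. Ccl2 had means of -0.76 in knockout and 1.09 in wild type.

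Of the 30 gene lists, 12 passed camera at its preset correlation, and none did with the correlation estimated from the data. With fry 6 passed: cytokines and chemokines, immediate early genes, macrophage and monocyte markers, endoplasmic reticulum stress, endothelial markers and skeletal muscle markers. Exact permutation of list means, chosen after seeing the data, passed 5: cytokines and chemokines, macrophage and monocyte markers, endoplasmic reticulum stress, skeletal muscle markers, and NRF2 and antioxidant genes. Among 100 splits of the arrays into 5 and 5, the real one included, 24 gave 12 or more lists, so this number of lists did not exceed chance.

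**Figure D5:**
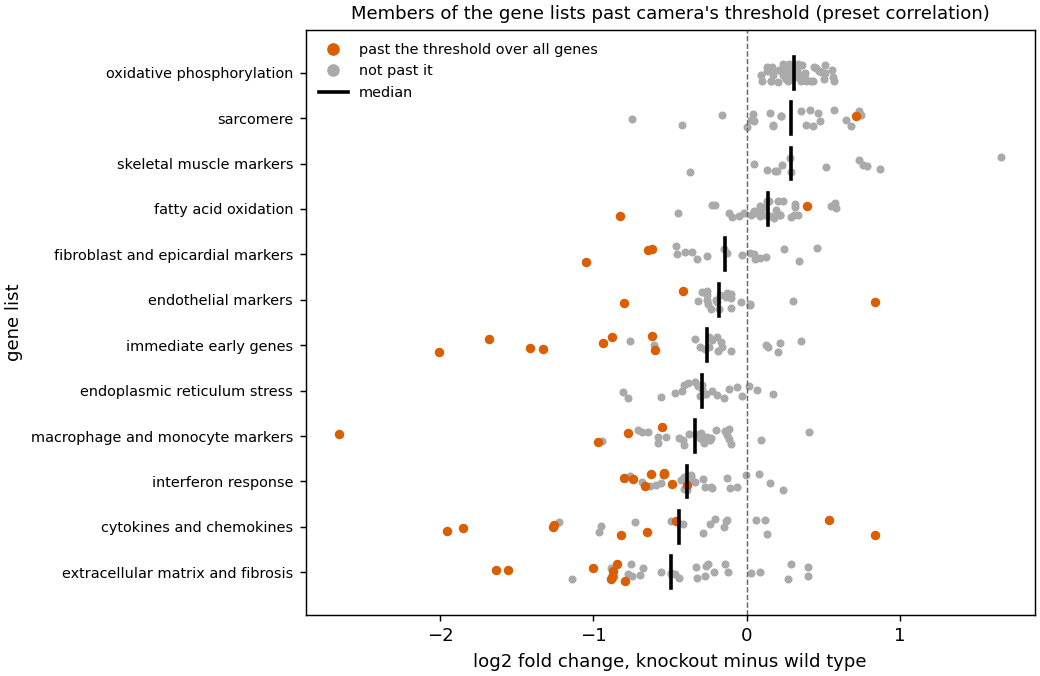
Log2 fold change, knockout minus wild type, of each measured member of the 12 lists past camera's threshold; orange members passed the threshold over all genes, grey ones did not, and the black bar is the list median. Medians ran from -0.50 for extracellular matrix and fibrosis to 0.31 for oxidative phosphorylation.

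Several chemokine genes fell in knockout hearts. Of 24 measured cytokines and chemokines, 7 fell, 2 rose and 15 did not pass (adjusted over the list alone, 10 fell and 2 rose), with a median log2 fold change of -0.44 (camera adjusted p = 1.49e-05). The list's adjusted p = 0.367 with an estimated correlation, and its median was -0.50 within slide 2 and -0.18 with normexp background correction. The monocyte attractants Ccl2 and Ccl7, neighbours on chromosome 11, fell as above. The chemokines Ccl9 (-1.26 ± 0.15, adjusted p = 0.00492) and Ccl6 (-1.26 ± 0.16, adjusted p = 0.00625) fell by similar amounts. Ccl2, Ccl7, Ccl9 and Ccl6 held their calls with every array left out in turn, within slide 2 and with the atrial score as a covariate. With atrial and fat scores as covariates, 1 of the 23 called falls in this list and the matrix and immediate early lists passed. The 2 rises were Tnf, an inflammatory cytokine (0.54 ± 0.12, adjusted p = 0.0386), chosen after its value was seen, and the lymphoid chemokine Ccl21a (0.84 ± 0.17, adjusted p = 0.0266).

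Some macrophage and monocyte markers fell too. Of 31 measured, 4 fell and none rose (adjusted over the list alone, 20 fell), and 29 had values below 0, with a median of -0.34 (camera adjusted p = 6.04e-09; adjusted p = 0.367 with an estimated correlation). Besides Clec4d, the falls were the fractalkine receptor Cx3cr1 (-0.97 ± 0.22, adjusted p = 0.034), the scavenger receptor Cd163 (-0.77 ± 0.18, adjusted p = 0.0389) and the Fc receptor chain Fcer1g (-0.55 ± 0.14, adjusted p = 0.0488). The calls of Cx3cr1, Cd163 and Fcer1g held in 3, 2 and 1 of the 10 fits with an array left out, with adjusted p up to 0.078 without wild-type replicate 4 for Cx3cr1, and 0.0841 for Cd163 and 0.108 for Fcer1g without wild-type replicate 2. Within slide 2, Cd163 and Fcer1g had adjusted p of 0.0764 and 0.116. The list median was -0.36 within slide 2. The 9 core macrophage markers had values from -0.58 to -0.13 and none passed over all genes. Of 16 neutrophil markers, 1 rose, Elane (0.60 ± 0.15, adjusted p = 0.0443), with a list median of -0.41 (camera adjusted p = 0.0836). Of 14 lymphocyte markers, 1 rose, Cd4 (0.62 ± 0.16, adjusted p = 0.0491), with a median of 0.39 (camera adjusted p = 0.0974). Elane held its call in 1 and Cd4 in none of the 10 fits with an array left out, with adjusted p up to 0.0994 and 0.107 without wild-type replicate 2.

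Some interferon-induced genes fell. Of 34 measured, 8 fell, none rose and 26 did not pass (19 fell when adjusted over the list alone), with a median of -0.39 (camera adjusted p = 4.66e-09; adjusted p = 0.482 with an estimated correlation, 0.0579 with fry and 0.0916 with exact permutation). The falls included Isg15, a ubiquitin-like modifier (-0.80 ± 0.17, adjusted p = 0.0325), the oligoadenylate synthetase-like genes Oasl1 (-0.74 ± 0.16, adjusted p = 0.0285) and Oasl2 (-0.66 ± 0.15, adjusted p = 0.0329), and Ifit1 (-0.54 ± 0.12, adjusted p = 0.0305). Within slide 2 the list median was -0.50. These 4 calls were lost in 6 or 7 of the 10 fits with an array left out, with adjusted p up to 0.0758 for Oasl2 without wild-type replicate 4, and Oasl1 missed the threshold within slide 2 (adjusted p = 0.0574). With normexp correction Ifit1 lost its call (-0.27 ± 0.09, adjusted p = 0.0519). Wild-type replicate 1 had the lowest list mean of its group, 0.07, against 0.53 to 0.69 in the other 4. The macrophage score, given above, was also lower in knockout.

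Genes of the extracellular matrix formed the list with the lowest median. Of 35 measured, 8 fell, none rose and 27 did not pass (16 fell when adjusted over the list alone), with a median of -0.50 (camera adjusted p = 5.73e-08; adjusted p = 0.482 with an estimated correlation). Col4a1, a basement membrane collagen, fell by 0.87 on the log2 scale (SE 0.10, adjusted p = 0.00409), and the metalloproteinase inhibitor Timp1 was 3.11-fold lower (-1.64 ± 0.28, adjusted p = 0.0152). The collagen cross-linking enzyme Lox (-0.88 ± 0.15, adjusted p = 0.0147) and fibrillin, Fbn1 (-0.88 ± 0.18, adjusted p = 0.0271), fell too; Fbn1 lost its call in 5 of 10 fits with an array left out (adjusted p up to 0.0661, without wild-type replicate 4) and within slide 2 (adjusted p = 0.0632). The list median was -0.66 within slide 2. Of 20 fibroblast and epicardial markers 3 fell and none rose (4 fell and 1 rose when adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.0264; adjusted p = 0.615 with an estimated correlation). They were the microfibril protein Mfap5 (-1.05 ± 0.15, adjusted p = 0.00905), Fbln2 (-0.65 ± 0.12, adjusted p = 0.018) and Ly6a (-0.62 ± 0.08, adjusted p = 0.00879), and all 3 held with every array left out in turn. The fat score was lower in knockout beside both lists (-4.24 against -2.34), and the fibroblast list's call was lost with quantile normalization (adjusted p = 0.0527), with array weights (0.147), with the atrial score (0.11), with atrial and fat scores (0.201), without knockout replicate 1 (0.179) and without knockout replicate 4 (0.127).

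Several immediate early genes, which are transcribed within minutes of a stimulus, fell. Of 26 measured, 8 fell, none rose and 18 did not pass (the same number, 8, when adjusted over the list alone), with a median of -0.26 and a mean of -0.47 (camera adjusted p = 2.23e-05; adjusted p = 0.367 with an estimated correlation and 0.068 with exact permutation). Besides Egr3, the transcription factor Egr2 was at least 2.9-fold lower (adjusted p = 0.00944) and not well above background on 2 of 5 knockout arrays. With normexp correction Egr2 was 1.53-fold lower, less than that bound (-0.61 ± 0.13, adjusted p = 0.0152), and Egr3 lost its call (-0.17 ± 0.13, adjusted p = 0.365). Junb, an AP-1 subunit, was 1.92-fold lower (-0.94 ± 0.13, adjusted p = 0.00904) and Maff 1.84-fold lower (-0.88 ± 0.15, adjusted p = 0.0147). Egr3, Egr2, Junb and Maff held their calls with every array left out in turn and within slide 2, where the list median was -0.35. With the atrial score as a covariate Egr3 passed, while Egr2, Junb and Maff did not (adjusted p = 0.0569, 0.0527 and 0.074).

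Mitochondrial and contractile genes had higher values in knockout, a shift that depended on the scaling, beside lower fat scores (-4.24 against -2.34) and macrophage scores (1.69 against 2.04). All 49 measured genes of oxidative phosphorylation had positive values with a median of 0.31, but none passed over all genes and 24 rose when adjusted over the list alone (camera adjusted p = 9.52e-11; adjusted p = 0.615 with an estimated correlation). The ATP synthase gene Atp5h was 0.36 ± 0.10 higher (adjusted p = 0.0662) and the cytochrome oxidase gene Cox6a2 0.49 ± 0.15 higher (adjusted p = 0.0791), and both turned negative with quantile normalization, -0.05 and -0.01. The list median was then 0.02 (camera adjusted p = 0.474), and it was 0.19 within slide 2. Of 24 sarcomere genes, 1 rose, Tcap, which caps titin at the Z-disc (0.72 ± 0.15, adjusted p = 0.0301), and 10 rose and 1 fell when adjusted over the list alone. Their median was 0.29 (camera adjusted p = 0.0016; adjusted p = 0.615 with an estimated correlation), 0.03 with quantile normalization (camera adjusted p = 0.604) and 0.22 within slide 2. The sarcomere call was also lost with normexp (0.141), without the filter on dim probes (0.174) and with slide and row (0.0712). Tcap held in 3 of 10 fits with an array left out (adjusted p up to 0.0714, without wild-type replicate 4). It missed the threshold with quantile normalization (0.22 ± 0.11, adjusted p = 0.216), with slide as a block (adjusted p = 0.0586) and within slide 2 (adjusted p = 0.086). Of 14 measured skeletal muscle markers 13 had positive values, and the median was 0.29 (camera adjusted p = 0.0106; adjusted p = 0.224 with an estimated correlation), 0.27 with quantile normalization and 0.37 within slide 2; none passed over all genes and 4 rose when adjusted over the list alone. This call was lost without the filter (0.174) and with slide and row (0.0712). Of the markers, Myl1 was 0.76 ± 0.21 (adjusted p = 0.0654) and Ryr1 0.52 ± 0.16 (adjusted p = 0.0852). Other Myl1 probes gave 1.01 ± 0.16, 1.47 ± 0.18 and 0.10 ± 0.17 (limma adjusted p over all kept probes of 0.0137, 0.00637 and 0.753).

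Fuel metabolism split between single genes. Ppargc1a, the coactivator that drives mitochondrial gene expression, fell by 0.82 (SE 0.17, adjusted p = 0.0301), and Acadm, a fatty acid dehydrogenase, rose by 0.39 ± 0.10 (adjusted p = 0.0468). They were the only 2 of 36 fatty acid oxidation genes past the threshold, over all genes as well as adjusted over the list alone. The list median was 0.14 (camera adjusted p = 0.0172; adjusted p = 0.615 with an estimated correlation), turned to -0.02 with quantile normalization (camera adjusted p = 0.836) and was 0.17 within slide 2. Its call was also lost with normexp (0.918), without the filter on dim probes (0.804) and with the atrial score as a covariate. The list lost its call in 4 fits with an array left out, knockout replicate 2 (0.0681), knockout replicate 4 (0.0527), wild-type replicate 2 (0.0502) or wild-type replicate 4 (0.067). Of 27 genes of glycolysis and glucose use 3 fell and none rose (3 fell and 4 rose when adjusted over the list alone): the glycolytic enzyme Pgam1 (-0.67 ± 0.12, adjusted p = 0.0162), glycogen synthase, Gys1 (-0.57 ± 0.11, adjusted p = 0.0241), and Pfkfb2 (-0.66 ± 0.14, adjusted p = 0.0319). The list median was 0.20 (camera adjusted p = 0.145) and -0.02 with quantile normalization. Without single arrays the calls of Ppargc1a, Gys1 and Pfkfb2 reached adjusted p of 0.0592, 0.0586 and 0.0708, each without wild-type replicate 5, and that of Acadm reached 0.0999 without wild-type replicate 2 and 0.332 with quantile normalization (0.11 ± 0.07). Within slide 2 none of Ppargc1a, Acadm, Pgam1, Gys1 and Pfkfb2 passed (adjusted p = 0.0507, 0.138, 0.0627, 0.0725 and 0.0524).

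Stress response lists differed in how many members passed. Of 31 NRF2 and antioxidant genes, 5 fell, none rose and 26 did not pass (7 fell and 1 rose when adjusted over the list alone), with a median of 0.02, a mean of -0.16 and camera direction downward (adjusted p = 0.197; adjusted p = 0.0476 with exact permutation). That mean rested on Hmox1, a gene picked after its value was seen that did not pass (adjusted p = 0.0687) and was well above background on 1 knockout array, and was -0.06 without it (exact permutation p = 0.119). The falls included sulfiredoxin, Srxn1 (-0.76 ± 0.11, adjusted p = 0.0108), Ugdh (-0.72 ± 0.12, adjusted p = 0.0135), thioredoxin reductase, Txnrd1 (-0.54 ± 0.10, adjusted p = 0.0228), and Abcc4 (-0.52 ± 0.11, adjusted p = 0.0281). Srxn1 and Ugdh held with every array left out in turn, while Txnrd1 reached adjusted p = 0.058 without wild-type replicate 5 and Abcc4 0.0631 without knockout replicate 2. The 23 genes of endoplasmic reticulum stress had a median of -0.29 with none past the threshold over all genes and 7 lower when adjusted over the list alone (camera adjusted p = 2.95e-05; adjusted p = 0.367 with an estimated correlation). Among them Dnajc3 was -0.31 ± 0.08 (adjusted p = 0.0565) and Atf4 -0.46 ± 0.14 (adjusted p = 0.072), and the list median was -0.35 within slide 2. The fat and macrophage scores, given above, were lower in knockout beside this list. Of 32 targets of p53, a substrate of HIPK2, 2 fell and 1 rose (6 and 4 when adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.337). The brighter probe of the cell cycle inhibitor Cdkn1a was 2.2-fold lower (-1.14 ± 0.24, adjusted p = 0.0285) and its other probe did not pass (-0.48 ± 0.22, adjusted p = 0.191), Plk2 fell (-0.71 ± 0.14, adjusted p = 0.0241) and Ddit4 rose as above. Cdkn1a and Plk2 missed the threshold within slide 2 (adjusted p = 0.0527 and 0.0549) and with some arrays left out (up to 0.0699 without wild-type replicate 4 and 0.058 without wild-type replicate 5).

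Vessel and clock genes were among the remaining changes. Of 23 endothelial markers 2 fell and 1 rose (5 and 1 when adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.00203; adjusted p = 0.16 with an estimated correlation) and -0.20 within slide 2. Fat and macrophage scores, given above, were lower in knockout beside these markers. The vascular growth factor receptor Kdr fell (-0.80 ± 0.13, adjusted p = 0.0147) and kept its call with every array left out in turn, whereas Emcn (-0.41 ± 0.10, adjusted p = 0.0433) reached 0.0985 and the rise of Ccl21a 0.0643 without wild-type replicate 4. In the circadian clock list of 20 genes, Arntl, a core activator of the clock, was 2.56-fold lower (-1.36 ± 0.17, adjusted p = 0.00658) and its partner Clock 1.46-fold lower (-0.55 ± 0.09, adjusted p = 0.0135). Both held with every array left out in turn and within slide 2, while the clock output gene Hlf rose (0.89 ± 0.22, adjusted p = 0.0478) and reached 0.103 without wild-type replicate 4 and 0.0725 within slide 2. The list median was 0.15 (camera adjusted p = 0.394), with 3 rises and 2 falls when adjusted over the list alone. The labels give no time of tissue collection.

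The other lists did not pass camera. The 14 genes of hypertrophy and the fetal programme had a median of -0.41 (adjusted p = 0.0561) with a fall of Uck2 (-0.97 ± 0.23, adjusted p = 0.0393), and 30 cell cycle genes a median of -0.20 (adjusted p = 0.0561) with falls of Birc5 (-0.48 ± 0.10, adjusted p = 0.0301) and Ccnb2 (-0.49 ± 0.12, adjusted p = 0.0435). Both lists passed within slide 2 (adjusted p = 2.97e-05 and 0.00244), as did calcium handling and ion channels (0.0129), neutrophil markers (0.0331) and smooth muscle and pericyte markers (0.041). With normexp the medians of cell cycle genes and neutrophil markers turned to 0.045 and 0.036 (adjusted p = 0.832 and 0.518). Birc5 was then -0.26 ± 0.08 (adjusted p = 0.0486), and Ccnb2 lost its call (-0.11 ± 0.10, adjusted p = 0.464). Lists that passed camera with normexp but not in the main fit were NRF2 (0.000811), hypertrophy (0.00178), lymphocyte markers (0.00286) and HIPK family and partners (0.00423). Smooth muscle and pericyte markers (0.00563), hypoxia (0.0186) and heat shock (0.0216) did so too. In the hypoxia list of 20 genes the brighter probe of Plod2 rose (0.55 ± 0.09, adjusted p = 0.0159), its other probe was -0.09 ± 0.23 and the mean of both 0.23 ± 0.14 (adjusted p = 0.324), and the list median was -0.07 (adjusted p = 0.227). In 18 atrial and conduction markers Tbx3 fell (-0.56 ± 0.14, adjusted p = 0.04999) and the median was -0.31 (adjusted p = 0.118). In 16 adipocyte markers Slc36a2 rose (0.68 ± 0.15, adjusted p = 0.0362), with a median of -0.03 (adjusted p = 0.554). Medians were 0.13 in 26 calcium handling and ion channel genes (adjusted p = 0.227), -0.17 in 19 Wnt and beta-catenin targets (0.0748), -0.05 in 21 heat shock genes and chaperones (0.598), -0.03 in 17 smooth muscle and pericyte markers (0.24) and 0.18 in 11 erythroid markers (0.554), with no member past the threshold over all genes. Among their members with the smallest p, Kcnh2 was 0.60 ± 0.16 (adjusted p = 0.0554), Myc -0.62 ± 0.16 and Cd44 -0.70 ± 0.22 (0.0539 and 0.0805), and Hspa1a -0.80 ± 0.28 and Hsp90aa1 -0.74 ± 0.26 (0.106 and 0.11). The other Kcnh2 probe was 0.53 ± 0.12 (limma adjusted p over all kept probes of 0.0367). Cspg4 was -0.48 ± 0.15 and Pdgfrb -0.49 ± 0.16 (0.0852 and 0.0888), Bpgm 0.25 ± 0.09 and Hba-a2 0.34 ± 0.13 (0.104 and 0.132), and Hba-a2 turned to -0.06 with quantile normalization. Of 25 HIPK family members and partners, the NF-kappaB subunit Rel fell (-0.44 ± 0.10, adjusted p = 0.0329), with a median of -0.06 (adjusted p = 0.15). Of 24 genes near Hipk2 on chromosome 6, Tbxas1 fell (-0.66 ± 0.16, adjusted p = 0.0441), with a median of -0.01 (adjusted p = 0.554). The brighter Plod2 probe kept its call with every array left out in turn but had adjusted p = 0.0537 within slide 2. The calls of Uck2, Birc5, Ccnb2, Tbx3, Slc36a2, Rel and Tbxas1 were each lost in at least 6 of the 10 such fits, with adjusted p up to 0.0989 for Tbxas1 without wild-type replicate 2.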

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

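The tests of slide, row and macrophage share below were chosen after the results were seen. Those of tissue scores and of chromosome 4 address patterns first seen in these results. Of 100 splits of the 10 arrays into 5 and 5, the real one included, 1 gave as many as 1017 genes past the threshold, and the highest other split gave 2. The same held for genes higher in knockout (1 split, 405 against 2), genes lower (1 split, 612 against 2) and genes changed at least 2-fold (1 split, 145 against 2). With 100 of 126 possible splits drawn, chance alone was unlikely for these counts. The other splits mix the genotypes, so any difference between the groups, whatever its cause, lowers their counts. For gene lists past camera at its preset correlation chance was not excluded: 24 splits gave 12 or more, and the highest other gave 19.

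The 1017 genes could also come from how arrays were placed, since wild-type replicates 1 and 2 alone filled slide 1 and the genotypes were uneven across rows. Within slide 2, 458 genes passed, while the highest of the other splits of its 8 arrays gave 1. This argues against the slide as the whole cause. Of these 458 genes, 338 were among the 1017, and a part of the slide in the others stays open. Lower signal of the knockout arrays was argued against as the whole cause by the share called among probes well above background on all 10 arrays, 7.25% against 4.94%. Its part is open, since rises made up 49.4% of those calls against 39.8%, and 3.18% of the 4122 brightest genes passed against 5.29% of the 4122 dimmest. The row of the array cannot be told apart from genotype, because knockout replicate 1 is the only array that shares slide and row with arrays of the other genotype. The row 2 arrays gave 352 called genes, but their wild-type arrays lay on slide 1 and their knockout arrays on slide 2. Over these genes knockout replicate 1 differed from the row 1 wild-type arrays by a signed median of 0.274 in the same direction. The largest such difference of a wild-type array was 0.092. In knockout replicate 1, 86.1% of these genes had the same sign, against 61.3% of all genes. With slide and row as covariates, a fit whose genotype term rests on that array, the 1017 genes had a median of 0.607 against 0.615, but none passed as the median SE rose from 0.127 to 0.213 (2788 genes at an unadjusted p under 0.05 in limma). Knockout replicate 1 and the row 1 wild-type arrays also helped to choose the 1017 genes. This favours a kept size, so the 0.607 does not separate row from genotype. The 0.274 comes from genes chosen without these arrays. A difference due to the genotype, or to litter or age, which were not tested, stays open.

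The lower chemokine, matrix and immediate early genes might reflect tissue composition. Their 23 members past the threshold had a median of -0.94, and -1.015 with atrial and fat scores as covariates. These members were chosen for passing without the scores, which favours genes that do not follow them. The test therefore cannot decide whether atrial or fat tissue was the source. With those covariates 23 of 23 were still lower and 1 passed the threshold, and the median SE grew from 0.18 to 0.23. Why the other calls were lost was not tested. All 85 measured members of the 3 lists had a mean of -0.50 against -0.36 for 9 core macrophage markers, a difference of -0.14 (exact permutation p = 0.206), so a lower share of macrophages stays open, as does an effect of the kinase on these genes.

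Fam205a2 fell and Ccl21a rose within the same part of chromosome 4, which could be a segment that differs between the mice. Of 95 other genes within 2 Mb of either probe 8 passed the threshold, 8.42% against 4.91% elsewhere (Fisher exact p = 0.145), which leaves this open. Whether these probes bind related sequences elsewhere was not checked.

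A gap statistic singled out 11 of 254 groups of 5 values, where chance singles out about 1 in 20, or 12.7. Each value is the share of the group's range that lies between 1 array and its nearest neighbour. In knockout, replicate 1 stood apart for Ccl9 (0.712; 1.56 against 1.18 to 1.29). Replicate 3 stood apart for Cd4 (0.741; 1.19 against 0.46 to 0.65), Slc36a2 (0.713; 1.58 against 2.09 to 2.30), the skeletal muscle list (0.808; 1.02 against 0.57 to 0.65) and E1A control spots (0.804; 10.55 against 10.73 to 10.78). Replicate 5 did for Mfap5 (0.761; 3.12 against 2.66 to 2.77) and the atrial and conduction list (0.94; 0.39 against -0.68 to -0.61). In wild type, replicate 4 stood apart for Clec4d (0.782; 0.32 against -1.36 to -0.99) and replicate 1 for the interferon list (0.731; 0.07 against 0.53 to 0.69). Replicate 3 did for Eppk1 (0.735; -3.95 against -2.87 to -2.49) and Pgam1 (0.926; 4.62 against 5.04 to 5.07).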

How the results depend on the processing

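The fits within slide 2, with slide and row, and with tissue scores, and the exact permutation of list means, were chosen after seeing the data. Genes higher in knockout numbered 2233 with normexp, 92 without a filter on dim probes, 1242 with array weights, 246 with slide as a block, 140 within slide 2, 26 with the atrial score and 3 with atrial and fat scores. Genes lower numbered 81 without the filter, 1508 with array weights, 318 within slide 2, 31 with the atrial score and 5 with atrial and fat scores. Genes changed at least 2-fold numbered 51 with normexp, 78 with signal asked for on all 10 arrays, 266 with array weights, 40 with the atrial score and 8 with both scores. With slide and row as covariates limma called 0 higher, 0 lower and 0 at least 2-fold (2788 at an unadjusted p under 0.05). All 1017 genes kept their direction in the fits with slide, slide and row, or tissue scores. Their median size was 0.615 without covariates (SE 0.127), 0.595 with the atrial score (0.15) and 0.599 with both scores (0.167). It was 0.599 with slide (0.136) and 0.607 with slide and row (0.213). These genes were chosen for passing without covariates, which favours a kept direction and size, so these values do not exclude any of the covariates.

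With each array left out in turn, genes higher ranged from 107 to 389, genes lower from 167 to 593, genes at least 2-fold from 77 to 159 and lists past camera from 10 to 16. The brightest Hipk2 probe ranged from -0.05 to 0.146 (-0.037, -0.012 and -0.018 in between), the second from 0.066 to 0.173 and the third from -0.042 to 0.031 (0.026 and 0.028 in between). Lists past the threshold numbered 21 without the filter, 0 with an estimated correlation, 6 with fry and 5 with exact permutation. Of 71 named genes past the threshold, 36 kept their call with every array left out. It held for 45 within slide 2 and for 57 with slide as a block, which share their fold changes and are not separate checks. In all of these fits 34 kept the call. Without the filter on dim probes 26 kept it, and with replicate number as a block 31. With the mean over a gene's probes 66 kept it, and Plod2, Cx3cr1 (adjusted p = 0.0517), Cd4 (0.0767), Tbx3 (0.0767) and Rel (0.0561) lost it. With quantile normalization 64 kept it, and Tcap, Acadm, Ddit4, Fcer1g, Cd4, Emcn and Tbx3 lost it. Of 28 such genes with several kept probes, 17 passed at every other probe; other probes of Adamts4 (-1.30), Tlr1 (-1.37), Cx3cr1 (-0.94), Ppargc1a (-0.67), Cdkn1a (-0.48), Cd4 (0.44), Pfkfb2 (-0.39), Clock (-0.36), Rel (-0.28), Tbx3 (-0.27) and Plod2 (-0.09) did not.

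As a replicate block, the shared numbers gave 46 higher, 118 lower and 74 at least 2-fold, with 161 of the calls shared. No sample correlated best with its own number (r from -0.106 to 0.05), a hint from the data and not from the design.

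Direction turned for the results below, of which only fatty acid oxidation was past the threshold, and the cause was not tested. The third Hipk2 probe was 0.114 with normexp, 0.069 with array weights, 0.095 with slide as a block and within slide 2, 0.175 with slide and row and 0.002 with both scores. For lists, the set test turned while the medians given here need not: calcium handling 0.086 with normexp and 0.106 without the filter; glycolysis 0.13, 0.196, and -0.02 with quantile normalization and the authors' table; erythroid markers 0.12, 0.191, -0.064 with quantile normalization and the table, 0.05 to 0.257 with an array left out (lowest without wild-type replicate 4), -0.057 with the atrial score and 0.007 with both scores. The circadian list was 0.124 without the filter, adipocyte markers 0.026 with signal on all 10 arrays and -0.032 with slide as a block. Heat shock genes were -0.025 without knockout replicate 5, -0.021 without wild-type replicate 4 and -0.029 with the atrial score (-0.096 to 0 with each array left out in turn), and fatty acid oxidation was 0.014 with both scores. With quantile normalization and the authors' table, Atp5h was -0.046 and -0.047, Cox6a2 -0.013 and -0.036, and Hba-a2 -0.064 in both.

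Signal over background limited dim probes: the unfiltered fit tested 37318 genes and called 173. Its median log2 fold change over all genes was 0.237, against 0.026 with the filter. For genes above background in wild type only, the fold is a lower bound under the main background subtraction. With normexp the folds of the named ones lay below it.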

Other observations

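These genes near Fam205a2 and Ccl21a on chromosome 4 were picked after their values were seen. The clone gene 4933409K07Rik fell by log2 2.37 (-2.37 ± 0.31, adjusted p = 0.0073). A transcript without a gene name fell too (-1.95 ± 0.33, adjusted p = 0.01535). B4galt1 (-0.58 ± 0.10, adjusted p = 0.0162) and Glipr2 (-0.67 ± 0.11, adjusted p = 0.0135) fell as well, while Dnaic1 (0.74 ± 0.12, adjusted p = 0.0133), Phf24 (0.51 ± 0.08, adjusted p = 0.014), Olfr159 (0.75 ± 0.15, adjusted p = 0.027) and Gm13304 (0.65 ± 0.16, adjusted p = 0.0412) rose.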
